A study of Arabidopsis thaliana with 12 samples.

How the data were processed

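The series holds 12 arrays of total leaf RNA, biotin-labelled, from Arabidopsis thaliana Col-0: 3 infected and 3 mock arrays at 18 h and the same at 48 h. Groups and replicate numbers were taken from the titles and treatment protocols. The deposited values are array intensity on a linear scale, computed with MAS5 per the submitters' processing notes; its version and settings are not given in the sources used here. The 2% trimmed mean of each deposited column was 100.0, so that the authors' scaling had set the arrays to one level, and this scaling was kept. Detection calls and scanner files were not used here, so that background is known only through the intensities.

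Intensities were converted to log2. The 64 control probe sets were left out of the tests, and of the other 22746 probe sets 15040 were tested: those at or above their array's 40th percentile (an intensity of 17.3 to 23.5) on at least 3 of 12 arrays. Genes were named through the platform annotation supplied with the series, updated through gene identifiers of the TAIR10.1 RefSeq table; 13436 identifiers matched and 77 kept the older name. Of the probe sets 13513 have 1 gene, 503 have several and 8730 are unnamed here, and genes were named only from probe sets with 1 gene. No coordinates are given because the sources name no genome build. The tested probe sets cover 8082 named genes; 88 genes had several probe sets, of which 20 disagreed in sign over both harvests, and none were called in opposite directions.

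One linear model with a mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 8 residual degrees of freedom and a median prior of 2.84. Benjamini-Hochberg adjustment was made within each contrast, and an adjusted p under 0.05 was the threshold. The contrasts, the lists, the rule for named genes and the alternatives were fixed before the data were examined: infection at 18 h, infection at 48 h, the difference between these, and mock leaves at 48 h against 18 h. A further contrast, infection over both harvests (the mean of both infection contrasts), was added after these 4 had given no call. Array-quality values were compared within a harvest by exact permutation, whose smallest two-sided p with 3 against 3 is 0.1.

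The rule for named genes took, per contrast, the 6 greatest rises and 6 greatest falls among called probe sets with 1 gene whose arrays did not overlap between groups, members of each gene list, and 6 marker genes, of which PDF1.2 and BIK1 were measured under a name here. After the planned contrasts had given no call, it was applied with an unadjusted p under 0.05 in those contrasts and with the adjusted threshold to infection over both harvests. For the difference between harvests no rises and falls were picked. List members were picked for infection over both harvests alone, and some others are named in the text outside the rule. Rises and falls were ranked by the change after raising values below each array's 40th percentile to that percentile. Folds and log2 differences given as at least a number, or on the floored scale where both groups hold arrays below the floor, use these values, because low MAS5 intensities have no reliable log. The tests used values without the floor.

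Of the 389 entries of 32 gene lists, 45 were measured under a name, in 21 lists. The 7 lists with 3 or more measured members were tested with camera at its preset correlation of 0.01, on 1 probe set per gene. A pooled list of light harvesting, Calvin cycle and chlorophyll synthesis genes, and 34 families of genes whose symbols share their leading letters or that belong to an organelle genome, were added after seeing the data. Camera with an estimated correlation and fry were alternatives; every camera call of a list or family was lost with an estimated correlation.

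Whether the title numbers pair infected and mock arrays was checked from the deviations from group means. At 18 h arrays of the same number deviated together (r = 0.140, 0.187 and 0.527 across probe sets), so that the numbers were taken as pairs there; the blocked fit also made 0 calls at 18 h. Arrays of first number 1 also deviated together across their second numbers: infected 1-1 with mock 1-2 (r = 0.210, above its own pair) and infected 1-2 with mock 1-1 (r = 0.141). The labels do not say what the numbers stand for.

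The alternatives were quantile normalization, centring on the 75th percentile, a pseudocount of 6.17, no filter, a filter at the 60th percentile, no intensity trend, array weights, only the groups compared, the title numbers as a block, leaving out each array, and, chosen after seeing the data, leaving out the 3 arrays that stand apart. The fit was tested on simulated data with 200 changed probe sets of 15040, in 5 simulations per contrast. At 2-fold and 4-fold it recovered 24.6% and 71.2% at 18 h, 21.2% and 64.8% at 48 h, 3% and 37.8% for the difference between harvests, 22.4% and 67.2% for mock leaves, and 50% and 80% over both harvests. False calls made up 4.77%, 6.93%, 4.23%, 4.07% and 4.27% of the calls. On 8082 simulated genes camera called a lowered list of 12 genes in 100% of 50 simulations and an unchanged one in 6%. All simulated values were drawn independently, with the same spread of a gene on every array. The rates from limma and camera therefore do not cover correlated genes or arrays of unequal quality.

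To place single arrays, an infection index and a harvest index were computed as means over 200 probe sets each, chosen and scaled on the arrays whose first title number is 2. On the infection index their mock arrays average 0 and their infected arrays 1, and on the harvest index their 18 h arrays average 0 and their 48 h arrays 1. The harvest index was built in 3 versions: one scaled on all other arrays, one on the arrays of first number 2, and the last also restricted to probe sets with an infected minus mock difference under 0.5 on the log2 scale in those arrays. Each later version was made after the earlier ones had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.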

Results

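Transcript abundance was measured in leaves of 4-week-old Arabidopsis thaliana Col-0 plants after inoculation with Botrytis cinerea, the grey mould fungus, a necrotroph that kills plant tissue and feeds on it. Inoculated leaves received 4 drops of 5 µl, each holding pre-germinated spores at 500000 per ml in potato dextrose broth, and mock leaves received drops of broth alone. Leaves were collected 18 h or 48 h later, giving 4 groups of 3 arrays, 12 arrays in all, each with a MAS5 intensity for 22746 probe sets besides 64 controls. Arrays carry a pair of numbers in their titles, such as 1-1 or 2-1, which the labels leave unexplained, and nothing in the labels says whether replicates came from separate plants or experiments. The p-values below therefore measure the spread between these samples, which may be technical. The median intensity per array lay between 28.6 and 38.1, and the number of arrays limits the precision of every value.

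The main axis of variation followed infection, and 3 arrays stood apart from their groups. The first principal component held 64.9% of the variance. Infected 48 h arrays 2-1 and 2-2 scored -146 and -129 on it, while infected 48 h array 1-1 scored only -26.6. Among infected 18 h arrays, 1-1 scored -76.3 and the others 29.8 and 43.7, and the mock arrays lay between 28.1 and 80.5. On the second component, with 10.1% of the variance, mock 48 h array 1-1 scored -35.6, while mock 48 h array 2-1 scored 50.3 with array 2-2 close to it. This component largely followed the first title number. Arrays of first number 2 scored from 3.03 to 50.3. Those of first number 1 scored from -35.6 to -23.2, apart from infected 48 h array 1-1 at 19.3. The 3 arrays that stood apart all carry the numbers 1-1. Mock 48 h array 1-1 correlated most closely with infected 18 h array 1-2 (r = 0.963 across probe sets, which are not independent replicates).

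**Figure D1:**
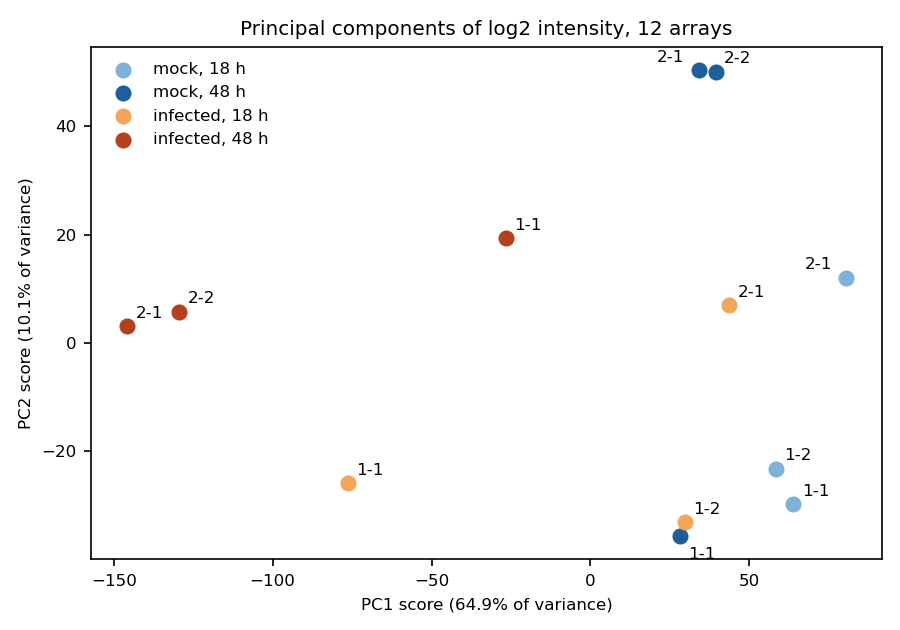
Scores of the 12 arrays on the first principal component (horizontal, 64.9% of the variance) and the second (vertical, 10.1%), coloured by group and marked with the numbers in their titles. Infected 48 h arrays 2-1 and 2-2 lie at -146 and -129, and mock 48 h array 1-1 lies at 28.1 on the first and -35.6 on the second.

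The first comparison asked which leaf transcripts differ from mock 18 h after inoculation. No probe set passed the adjusted threshold, and the values of single genes are given without a call. With values below each array's 40th percentile, taken as background, raised to it, the greatest difference was that of AT4G16260, at least 34.9-fold. This gene, of the beta-glucanase family that degrades fungal wall glucan, had a mean log2 intensity of 10.44 ± 1.31 (SD, n = 3) in infected and 5.08 ± 1.22 in mock leaves, a log2 difference of 5.35 ± 0.89 (SE; limma adjusted p = 0.148). The FAD-linked oxidoreductase gene AT1G26380 was at least 18.1-fold higher, with the smallest adjusted p of this comparison, 0.0925. On the floored scale the class III peroxidase gene Prx37 was at least 14.1-fold, AT1G68620 at least 11.1-fold, and AT4G01870 and the chitinase gene CHI at least 10.1-fold higher; Prx37 and AT1G68620 were below the floor on all 3 mock arrays. Infected array 1-1 carried much of this: without it AT4G16260 was 21.1-fold, AT1G68620 3.96-fold, CHI 5.07-fold and AT4G01870 4.65-fold higher on the floored scale. Lower values in infected leaves were smaller in size: -1.56 ± 0.70 for AT5G48490, of the lipid transfer protein family, -1.21 ± 0.44 for the tetraspanin gene TET10 and -1.10 ± 0.39 for AT1G79720. AT5G15780, AT1G56720 and CYTC6A, which encodes a chloroplast cytochrome, were 2.43-fold, 2.30-fold and 2.18-fold lower on the floored scale, and without infected array 1-1 AT1G56720 and CYTC6A were 1.82-fold and 1.57-fold lower. Without that array TET10 and AT1G79720 differed by only -0.68 and -0.66, and AT5G48490 by -1.41. The rule that chose these 12 genes asked that infected and mock arrays not overlap, and their adjusted p ran from 0.0925 to 0.676. The defensin gene PDF1.2, a marker of joint jasmonate and ethylene signalling, differed by 3.06 ± 0.62 (adjusted p = 0.192), and the receptor-like kinase gene BIK1 by 0.35 ± 0.41 (adjusted p = 0.760).

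Among the gene lists at 18 h, the 3 measured antimicrobial protein genes had a median log2 difference of 3.46 (2.23 on the floored scale) and the 4 pattern recognition genes one of 0.70, both with a camera adjusted p of 0.0906. No member passed over all probe sets, and adjusted over the list alone 1 antimicrobial gene did. The antimicrobial median is the value of OSM34, which was above the floor on infected array 1-1 alone (log2 difference 0.04 on the floored scale without that array). Without mock 18 h array 1-1 both lists passed (adjusted p = 0.0426 for antimicrobial and 0.00991 for pattern recognition genes). Of the 12 photosynthesis genes in the pooled lists 11 were lower, with a median of -0.38 (camera adjusted p = 0.545). The camera adjusted p was 0.439 for the listed stress WRKY genes, 0.545 for light harvesting, 0.828 for Calvin cycle, and 0.997 for both auxin and chlorophyll synthesis genes. In limma, 0 of 15040 probe sets were called in either direction, 1105 had an unadjusted p under 0.05 (722 higher, 383 lower) and 752 would by chance. All infected arrays lay above all mock arrays at 1146 probe sets and below at 1348, against 752 expected each way. With array weights 48 probe sets were higher and 2 lower, without infected 48 h array 1-1 the counts were 6 and 0, without mock 48 h array 1-1 they were 13 and 0, and without the 3 arrays that stand apart, picked after seeing the data, 75 and 0.

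The comparison at 48 h addressed the later stage of infection. No probe set passed here either, and the 12 photosynthesis genes measured were lower, GSA1 by only 0.01. JRG21, which encodes an oxidase that inactivates jasmonic acid, had the greatest positive difference on the floored scale, at least 54.0-fold (limma adjusted p = 0.0535). The osmotin-like gene OSM34 was at least 50.3-fold, the pectin methylesterase inhibitor gene AT1G62760 at least 43.8-fold, AT4G23680 at least 32.2-fold, AT1G76470 at least 31.0-fold and AT2G38240, for a further jasmonic acid oxidase, at least 29.9-fold higher. In the other direction AT2G10940 differed by -4.44 ± 0.90 on the log2 scale (SE, n = 3 and 3), from a mean log2 intensity of 10.08 ± 0.17 (SD) in mock to 5.64 ± 2.27 in infected leaves. AT5G44020, AT3G16370, AT3G06070 and AT2G29290 differed by -3.54, -3.38, -3.37 and -3.35, and AT2G34620 was at least 10.7-fold lower. Without the 3 arrays that stand apart the 6 positive differences were 43.4-fold to 88.8-fold on the floored scale, and AT2G10940, AT3G16370, AT5G44020, AT3G06070 and AT2G29290 had differences from -5.66 to -4.29, in this order of size. PDF1.2 differed by 1.65 ± 0.62 (adjusted p = 0.0925; 2.57 and 0.00704 without those arrays) and BIK1 by 0.93 ± 0.41 (adjusted p = 0.133; 1.36 and 0.0205 without them, and 0.00195 with array weights).

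Gene lists passed at 48 h although single genes did not. The pooled photosynthesis list had a median log2 difference of -1.88 over its 12 measured genes (camera adjusted p = 1.74e-04; adjusted p = 0.263 with an estimated correlation), and 11 of them passed adjusted over the list alone. Light harvesting and photosystem genes (6 of 6 lower, median -1.49, camera adjusted p = 0.00499) included PSAN at -2.59 ± 0.74 and LHCB4.2 at -1.98 ± 0.72. Calvin cycle genes (3 of 3 lower, median -2.26, camera adjusted p = 0.0183) were SBPASE at -2.91 ± 0.71, PRK at -2.26 ± 0.57 and RCA, the Rubisco activase gene, at -1.44 ± 0.41. With an estimated correlation both lists also had an adjusted p = 0.263. Adjusted over the list alone all 6 and all 3 passed, as did 2 of the 3 chlorophyll synthesis genes, whose camera adjusted p was 0.148. The 3 antimicrobial genes had a median of 3.52 (camera adjusted p = 0.0187; adjusted p = 0.243 with an estimated correlation), and 2 passed adjusted over the list alone. That call was lost without infected 48 h array 1-1 (adjusted p = 0.0678). Of the antimicrobial genes, THI2.1 differed by only -0.02 on the floored scale. Pattern recognition genes, all 4 higher, had a median of 1.06 (camera adjusted p = 0.0367; adjusted p = 0.263 with an estimated correlation), a call lost under quantile normalization (0.0637), 75th percentile centring (0.0541), the stricter filter (0.0759), and without infected 48 h array 2-1 (0.109) or the 3 arrays that stand apart (0.0512). The 3 listed stress WRKY genes had a median of 0.95 and a camera adjusted p of 0.0524, and the 3 auxin genes one of 0.374 with members in both directions. All 5 measured genes with a WRKY symbol, grouped after seeing the data, had a median of 0.72 at 48 h and -0.06 at 18 h. Adjusted over the list alone, 1 WRKY gene was higher, 1 auxin gene was higher and 1 lower, and no pattern recognition gene passed. In fry, a test against no change, the pattern recognition call was also lost (adjusted p = 0.116), and chlorophyll synthesis genes passed (0.031). On the same arrays the 3′ to 5′ ratio of the ubiquitin control, a sign of RNA integrity, was 1.32 ± 0.05 (SD, n = 3) in infected and 1.51 ± 0.12 in mock leaves (two-sided exact permutation p = 0.1, the smallest possible here). The same ratio ran the other way for GAPDH (1.60 against 1.52, exact permutation p = 0.6) and actin (1.54 against 1.42, exact permutation p = 0.5).

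In limma no probe set passed at 48 h, where the smallest adjusted p was 0.0514, while 5289 had an unadjusted p under 0.05 (2169 higher, 3120 lower) against 752 by chance, and 1647 higher and 2405 lower had an adjusted p under 0.1. Single arrays decided this count: without infected 48 h array 1-1, 1991 probe sets were higher and 3301 lower; without infected 18 h array 1-1, which adds only to the shared spread, 1469 and 1844; without mock 48 h array 1-1, 13 and 7; and without infected 48 h array 2-1, 0 and 1. Array weights gave 3411 and 4692, the stricter filter 604 and 830, and leaving out the 3 arrays that stand apart, a choice made after seeing the data, 2617 and 3885.

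**Figure D2:**
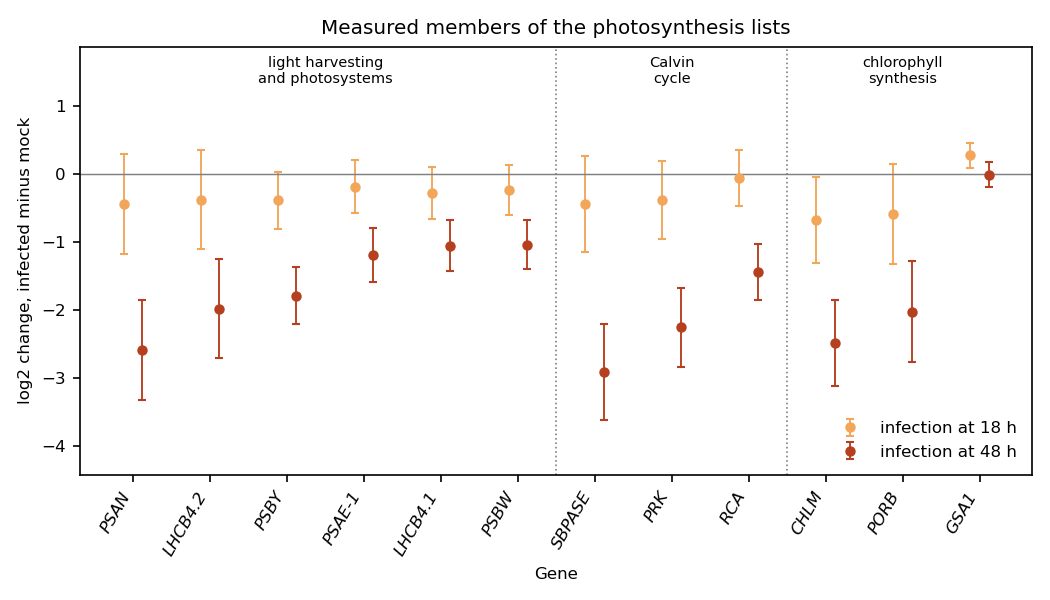
Log2 difference, infected minus mock, of the 12 measured genes of the photosynthesis lists at 18 h and 48 h; points are estimates and bars their standard errors (n = 3 arrays per group). The median is -0.38 at 18 h and -1.88 at 48 h.

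Whether the response differed between harvests was tested as the difference of the infected minus mock differences, 48 h minus 18 h. Photosynthesis genes carried the lists that passed: all 12 were lower by more at 48 h, with a median of -1.42 (camera adjusted p = 8.78e-07; adjusted p = 0.240 with an estimated correlation). Light harvesting genes had a median of -1.20 (camera adjusted p = 7.56e-04) and Calvin cycle genes one of -1.87 (camera adjusted p = 0.00128), each with an adjusted p = 0.240 with an estimated correlation. These 3 calls were also lost in fry (adjusted p = 0.251 for the pooled list, 0.277 for light harvesting and 0.251 for Calvin cycle genes). Adjusted over the list alone, the 3 Calvin cycle genes passed and none of the other photosynthesis genes did. Chlorophyll synthesis (0.0535), stress WRKY (0.135), antimicrobial (0.143), auxin (0.267) and pattern recognition genes (0.284) did not pass. PDF1.2 had a difference of -1.41 ± 0.88 and BIK1 of 0.58 ± 0.58, both with an adjusted p of 0.902. Without the 3 arrays that stand apart these were -0.15 and 1.33, and with array weights BIK1 passed (adjusted p = 0.0368). In limma 0 probe sets were called, and 422 had an unadjusted p under 0.05 against 752 by chance. Array weights gave 1106 higher and 2080 lower, leaving out infected 48 h array 1-1 gave 6 and 439, leaving out infected 18 h array 1-1 gave 3 and 0, and leaving out the 3 arrays that stand apart gave 1284 and 2285. Across the 15040 probe sets the differences at 18 h and 48 h, which share no array, correlated with r = 0.789 and rho = 0.766; probe sets are not independent replicates. With 0 calls at each harvest, no overlap of calls could be assessed.

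Mock leaves were compared between 48 h and 18 h, where the title numbers are not balanced. They are 1-1, 1-2 and 2-1 at 18 h and 1-1, 2-1 and 2-2 at 48 h. Harvest is therefore partly mixed with the first number, and a difference here need not come from the harvest alone. AT4G16260 was at least 8.64-fold and AT1G26380 at least 3.79-fold higher at 48 h on the floored scale, and PDF1.2 had a log2 difference of 2.19 ± 0.62 (SE, n = 3 and 3), each with a limma adjusted p of 0.576. AT5G18470 differed by 1.92, and AT2G23680 and AT1G76960 were at least 3.46-fold higher. The lower transcripts were AT4G18970, AT3G05900, AT1G22570, AT2G30600, AT4G34220 and AT1G75960, with differences from -2.33 to -1.61, and BIK1 differed by -0.05 ± 0.41 (adjusted p = 0.990). AT4G16260 had an intensity of 117 and 293 on mock 48 h arrays 2-1 and 2-2 and of 1177 on array 1-1, which stands apart; without that array it was 4.67-fold and AT1G26380 2.42-fold higher on the floored scale, and AT2G30600 and AT3G05900 differed by -2.36 and -2.38. No list passed: the pooled photosynthesis genes had a median of -0.41 (camera adjusted p = 0.217), light harvesting genes 0.188, and the other lists 0.695 or more. The pooled list reached 0.00839 with array weights, 0.0015 with only the groups compared, 0.00173 without infected 48 h array 1-1 and 3.38e-05 without the 3 arrays that stand apart. The mock 18 h arrays enter both this comparison and the one of infection at 18 h. In limma 0 probe sets were called, 1179 had an unadjusted p under 0.05 (754 higher, 425 lower) and 752 would by chance. Array weights gave 1087 higher and 1035 lower, leaving out mock 48 h array 1-1 gave 16 and 32, and leaving out the 3 arrays that stand apart 447 and 518. Leaving out arrays in these ways keeps only mock 48 h arrays of first number 2, against 18 h arrays mostly of first number 1.

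Because none of the 4 planned comparisons made a call, infection was also tested over both harvests, 6 infected against 6 mock arrays with the harvests kept apart, a comparison added after those counts were seen. AT4G16260 rose at least 19.7-fold (limma adjusted p = 0.0161), AT1G26380 at least 11.4-fold (adjusted p = 0.0125) and CHI at least 11.2-fold (adjusted p = 0.0229) on the floored scale. AT1G68620, AT4G01870 and AT1G76470 rose at least 18.0-fold, 13.4-fold and 11.3-fold. STOMAGEN, which encodes a secreted peptide that promotes stomata, fell by at least 1.81 on the log2 scale (adjusted p = 0.0339), and PSB27, for a photosystem assembly protein, fell by 1.78 ± 0.50 (SE; adjusted p = 0.0467). AT2G29290 and AT3G20820 fell by 2.09 and 1.79, and AT3G23880 and AT4G38690 by at least 1.83 and 1.81.

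**Figure D3:**
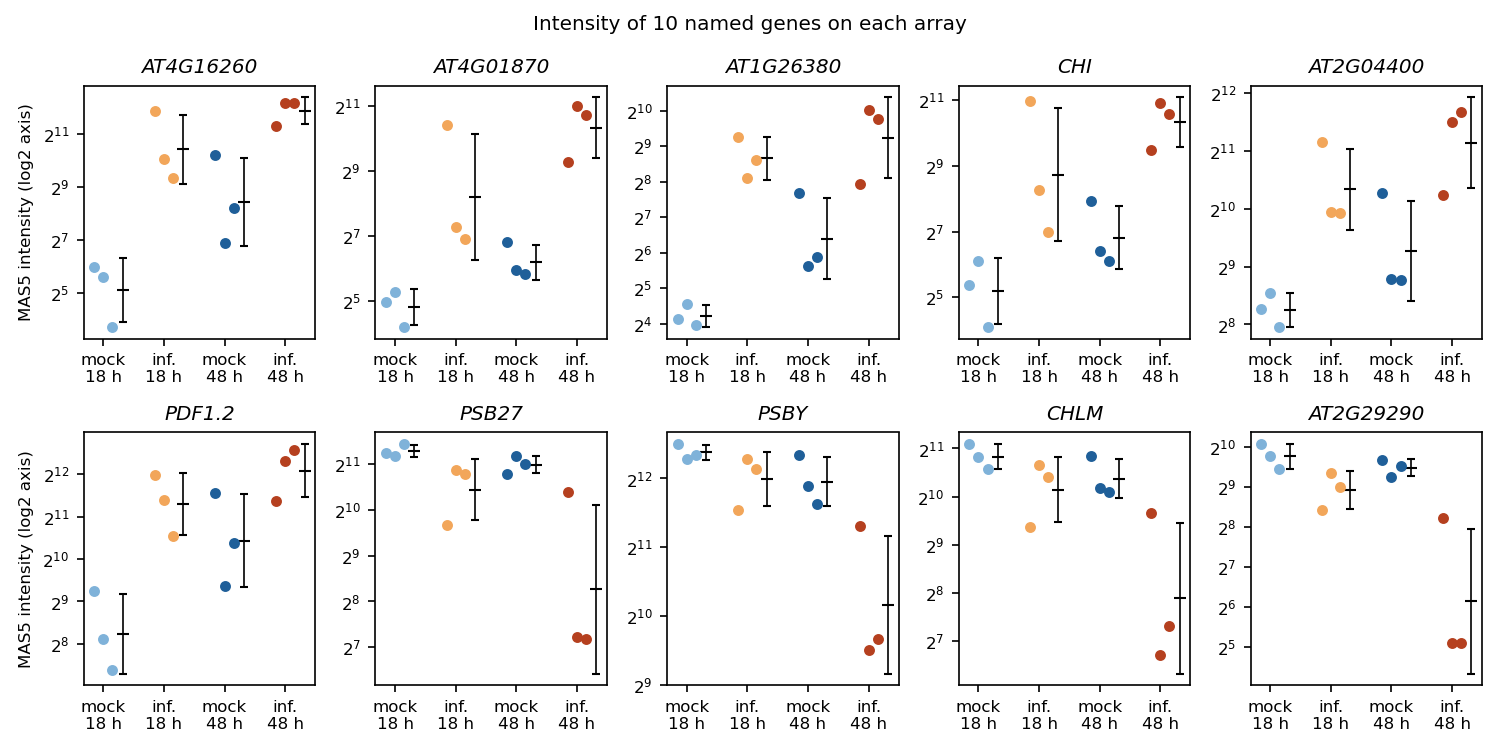
MAS5 intensity, on a log2 axis, of 10 named genes on each of the 12 arrays, by group; dots are arrays, and bars are the geometric mean ± SD of log2 intensity (n = 3). AT4G16260, the top rise, was at least 19.7-fold higher over both harvests, and PSB27 fell by 1.78 on the log2 scale.

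Of the 45 list genes measured, 12 rose, 3 fell and 30 did not pass over both harvests. In tryptophan synthesis the indole-3-glycerol phosphate synthase gene AT2G04400 rose by 1.97 ± 0.36, and in indole glucosinolate synthesis the glucosyltransferase gene UGT74B1 by 0.95 ± 0.20, each the single member of its list measured, while BCAT4, the single one of aliphatic glucosinolate synthesis, did not pass (-0.11 ± 0.49). PDF1.2 rose by 2.35 ± 0.44 and PDF1.2b by 1.54 ± 0.36, and the jasmonate synthesis gene OPCL1 by 1.16 ± 0.25. Whether the probe set of PDF1.2b reads that gene apart from PDF1.2 was not tested, so that these need not be separate rises. WRKY6 rose by at least 2.35 and the ubiquitin ligase gene PUB24 by 1.12 ± 0.31. They are 1 of 3 stress WRKY and 1 of 4 pattern recognition genes, the same counts as adjusted over the list alone. All 5 measured genes with a WRKY symbol had a median of 0.23. OSM34 and CHI rose among the 3 antimicrobial genes, again 2 adjusted over the list alone. Rises called for OSM34, for CCR2 of lignin synthesis, for the glutathione transferase gene GSTU25 and for the senescence gene SAG29, which encodes a sugar transporter, rest largely on values below the floor, where these genes lay on all 6 mock arrays and on infected 18 h arrays 1-2 and 2-1. On the floored scale their differences were 3.94, 0.76, 2.58 and 1.78, and without the 3 arrays that stand apart those of OSM34 and SAG29 were 2.97 and 0.51. The SAG29 call was lost with a pseudocount (log2 difference 2.82, adjusted p = 0.0667). PSBY of photosystem II fell by 1.09 ± 0.30, CHLM of chlorophyll synthesis by 1.58 ± 0.45 and the expansin gene EXPA8 by at least 2.16. Values for COR15A (-0.30 ± 0.97, and -1.34 without the 3 arrays that stand apart), WES1 (0.38 ± 0.30), DFR (0.57 on the floored scale), CRT1b (0.53 ± 0.24), RCA (-0.75 ± 0.29), the clock gene GI (0.28 ± 0.45), the guard cell gene AT1G22690 (-1.29 ± 0.39) and BIK1 (0.64 ± 0.29) did not pass.

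Camera called 4 lists over both harvests. The pooled photosynthesis list had a median of -1.13 (adjusted p = 0.00638; adjusted p = 0.382 with an estimated correlation), with 2 of 12 members called and 11 adjusted over the list alone. Light harvesting genes (median -0.89, adjusted p = 0.0264) had 1 of 6 called and 6 adjusted over the list alone, and pattern recognition genes had a median of 0.88 (adjusted p = 0.0276); both had an adjusted p = 0.382 with an estimated correlation. Antimicrobial genes had a median of 3.53 (adjusted p = 0.0264; adjusted p = 0.251 with an estimated correlation), the only of these calls kept in fry (adjusted p = 0.00898, against 0.0731 for the pooled list and light harvesting genes and 0.0919 for pattern recognition genes). On the floored scale, which these tests did not use, OSM34 and CHI differed by 3.94 and 3.49 and THI2.1, the remaining member, by -0.02. The pattern recognition call was lost without infected 48 h array 2-1 (0.0571) and the antimicrobial call without infected 48 h array 1-1 (0.0547). Calvin cycle (0.0513), stress WRKY (0.0764), chlorophyll synthesis (0.361) and auxin genes (0.505) did not pass.

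In all, 995 probe sets rose and 872 fell over both harvests at a limma adjusted p under 0.05, of which 689 and 482 by at least 2-fold, and 931 of these 1867 probe sets name 1 gene. The risen probe sets had a median log2 difference of 1.12 at 18 h and 1.67 at 48 h, the fallen ones of -0.64 and -1.45. The count depended on single arrays: it was 0 in both directions without infected 48 h array 2-2, mock 48 h array 2-1 or mock 48 h array 2-2, where the smallest adjusted p was 0.0507, 0.0509 and 0.0525. It was 11 higher and 5 lower without infected 48 h array 2-1, 18 and 2 without mock 18 h array 1-1, 74 and 16 without mock 18 h array 1-2, and 116 and 69 without mock 18 h array 2-1. Without mock 48 h array 1-1 it was 459 and 197, without infected 18 h array 1-1 532 and 174, without infected 18 h array 2-1 1423 and 1439 and without infected 48 h array 1-1 2171 and 3442. All 1867 probe sets kept their direction in each of these fits. Each fit reuses all but 1 of the arrays on which the 1867 were chosen, so that this gives no independent support.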

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

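The pooled list was chosen after the result was seen, so that its tests with an estimated correlation and with fry were too, although both were planned for the single lists. The test without the 3 arrays that stand apart was set before its value was known, though those arrays were picked from the data. The photosynthesis lists drew attention because their response differed between the harvests: camera adjusted p was 8.78e-07 for the pooled list, 7.56e-04 for light harvesting genes and 0.00128 for Calvin cycle genes, with all 12 genes lower by more at 48 h (median log2 difference of differences -1.42). Without the 3 arrays that stand apart the camera adjusted p of the pooled list was 5.58e-09, in the same direction. That fit could not decide whether these arrays were the source. Infected 18 h array 1-1 lay further along the infection response than its group, and infected 48 h array 1-1 less far. Leaving those out tends to widen a difference between harvests. Correlation between the genes of the lists stays open as a source of the small p-values: with an estimated correlation the adjusted p was 0.240, so that the call was lost, as it was in fry (0.251). A progressive loss of photosynthetic transcripts as infection advances stays a hypothesis, which none of these tests decides. Intensities scaled to one level on each array show relative, not absolute, abundance. RNA integrity, the amount of living leaf tissue, the share of fungal RNA and the time of day at harvest were not tested as sources of this difference.

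Control probe sets, which the comparisons leave out, showed signal above mock. All infected arrays lay above all mock arrays at 6 of 19 Arabidopsis control probe sets at 48 h and 1 of 19 at 18 h, where chance gives 0.95 each (1 in 20) for independent probe sets, which these are not. Folds at 48 h were 1.87, 2.09, 2.23 and 1.77 for 4 GAPDH probe sets and 1.37 and 1.34 for ubiquitin probe sets, and at 18 h 1.21 for a ubiquitin probe set. Each stayed above 1 under quantile normalization and 75th percentile centring. Groups of 3 arrays are too small for a test of single outlying values.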

How the results depend on the processing

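No result turned its direction past the threshold under any alternative. Leaving out the 3 arrays that stand apart and every alternative for infection over both harvests were chosen after seeing the data, as were fits without an array of a group outside the contrast. Counts are given as probe sets higher and lower, and where no reason is named the cause was not tested. At 18 h the 0 and 0 of the model became 48 and 2 with array weights, 1 and 0 with only the groups compared, and 75 and 0 without the 3 arrays that stand apart; leaving out single arrays gave 0 to 13 higher and 0 lower. At 48 h it became 1 and 15 with quantile normalization, 2 and 26 with 75th percentile centring, 4 and 30 with a pseudocount, 604 and 830 with the stricter filter, which tests 10611 probe sets, 0 and 4 with no trend, 3411 and 4692 with array weights, 223 and 39 with only the groups compared, and 2617 and 3885 without the 3 arrays; single arrays left out gave 0 to 1991 higher and 0 to 3301 lower. The difference between harvests became 1106 and 2080 with array weights and 1284 and 2285 without the 3 arrays, with 0 to 6 higher and 0 to 439 lower when single arrays were left out. Mock leaves became 1087 and 1035 with array weights and 447 and 518 without the 3 arrays, with 0 to 16 higher and 0 to 32 lower. Infection over both harvests, 995 and 872, became 555 and 304 with no filter, 697 and 491 with no trend, 2698 and 3878 with array weights and 2146 and 3242 without the 3 arrays, of which 1835 were among the 1867; single arrays left out gave 0 to 2171 higher and 0 to 3442 lower. Quantile normalization (1040 and 856), 75th percentile centring (1065 and 891), the pseudocount (1121 and 1080) and the stricter filter (1151 and 1162) stayed within 1.5 times, and all 1867 kept their direction in every fit that tested the same probe sets. These fits reuse the arrays on which the 1867 were chosen, so that the kept direction gives no independent support. Probe sets called in the same direction at both harvests became 50 with array weights (11.5 expected from independent lists), 74 without the 3 arrays (13.1 expected), and 0 to 6 without single arrays.

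At 48 h arrays of the same title number did not deviate together (r = -0.165, -0.0474 and -0.118), so that the numbers are not taken as pairs there. With the full number as a replicate block the count at 48 h was 0 and 0, and over both harvests 623 and 542. With the first number alone as a replicate block it was 1013 and 1668 at 48 h and 1537 and 2067 over both harvests, and as a random block (correlation 0.128) 1006 and 1475 at 48 h and 1456 and 1764 over both harvests. The block changed no other count and no call of a list at 18 h; lists could not be run with a random block in camera.

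Some lists that did not pass came past the threshold in several alternatives: stress WRKY genes at 48 h (0.0137 with the full number as a block), chlorophyll synthesis genes for the difference between harvests (0.0257 with quantile normalization) and Calvin cycle genes over both harvests (0.0445 with quantile normalization). Over settings and contrasts, 947 values of lists stayed on their side of the threshold, 59 came past it, 27 were lost and 37 turned sign without a call; for families these numbers were 547, 30, 70 and 18, and for named genes 1592, 156, 297 and 15. The median of all probe sets at 48 h was -0.10 as deposited, -0.02 with quantile normalization and -0.03 with 75th percentile centring. Without detection calls, intensities under the 40th percentile give only bounds, which limits transcripts near background in mock leaves.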

Other observations

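Families of genes were grouped by symbol after the data were seen, and all tests in this part other than the counts of splits were chosen after the results were seen. Over both harvests the UGT family, glycosyltransferases that attach sugars to small molecules, was higher as a set (33 genes measured, median log2 difference 0.45, or 0.31 on the floored scale, camera adjusted p = 0.00326; adjusted p = 0.630 with an estimated correlation). Of these 10 rose and none fell over all probe sets, among them UGT76E12 (8.82-fold on the floored scale) and UGT73B4 (3.72-fold), both below the floor on all mock arrays and on 2 infected 18 h arrays. The IQD family, calmodulin-binding proteins of microtubules and membranes, was lower in all 9 measured genes (median -0.88, or -0.80 floored, camera adjusted p = 0.00326; adjusted p = 0.630 with an estimated correlation), and 4 fell, including iqd21 by at least 1.44 and IQD22 by at least 0.83. Both families passed in fry over both harvests (adjusted p = 0.0464 each), though not at 48 h (0.0917 each). Calmodulin-like CML genes were higher at 18 h (5 measured, median 0.69, camera adjusted p = 0.0254; adjusted p = 0.684 with an estimated correlation; fry adjusted p = 0.519). Over both harvests CML41 rose by at least 2.75 and CML42 by 0.52 ± 0.15, with a camera adjusted p of 0.0652 for the family, which passed in fry (0.0464), with no filter (0.0204) and without the 3 arrays that stand apart (0.0455). The 18 h calls of UGT, IQD and CML genes (0.0254, 0.0282 and 0.0254) were all lost without infected 18 h array 1-1 (0.273, 0.273 and 0.191) or mock 18 h array 2-1 (0.168, 0.0797 and 0.0970), those of IQD and CML genes without infected 18 h array 1-2 (0.0735 and 0.0726) and that of IQD genes without mock 18 h array 1-2 (0.103). They were also lost with array weights (0.177, 0.11 and 0.0914) and without the 3 arrays that stand apart (0.177, 0.177 and 0.0945).

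Genes of the organelle genomes were grouped as 2 sets, whose difference from each other was not tested. Over both harvests 63 of 69 measured chloroplast genome genes were lower (median -0.38, camera adjusted p = 0.00326; adjusted p = 0.770 with an estimated correlation; fry adjusted p = 0.157) and 5 fell, including the ribosomal protein gene rps18 by 1.29 ± 0.30 and the splicing factor gene matK by 0.98 ± 0.23. At 48 h this set had a median of -0.51 (camera adjusted p = 0.00475; adjusted p = 0.862 with an estimated correlation), a call lost without infected 48 h array 2-2 (0.333). Of 13 mitochondrial genome genes 11 were higher over both harvests (median 0.33, or 0.19 on the floored scale, camera adjusted p = 0.0316; adjusted p = 0.630 with an estimated correlation; fry adjusted p = 0.0932), with none past the threshold alone. That call was lost without infected 18 h array 1-1 (0.0513), infected 48 h array 2-1 (0.0857), mock 18 h array 2-1 (0.0554), mock 48 h array 1-1 (0.0633) or mock 48 h array 2-1 (0.0761), with the stricter filter (0.118), with array weights (0.0553) and with the probe set of largest variance per gene (0.0629). Mitochondrial genome genes were also higher in mock leaves at 48 h than at 18 h (median 0.42, camera adjusted p = 0.0388; adjusted p = 0.841 with an estimated correlation), a call lost in several alternatives, among them quantile normalization (0.0771).

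Other splits of the same arrays were counted. Over both harvests 1 of 100 splits, the real one, gave as many calls (1867, against 512 at the highest other). A chance assignment of these arrays is thus an unlikely source of that count, which was itself added after seeing the data. The splits treat arrays as exchangeable, although the labels do not say whether they came from separate plants. Chance differences between plants are therefore not excluded. For the difference between harvests 44 of 100 splits gave as many probe sets at an unadjusted p under 0.05 as the real 422, but this leaves open whether chance can be excluded, because splits that exchange infected and mock at one harvest bring the infection effect into this contrast. The highest other count, 5696, came from such a split, which exchanges all 6 arrays at 48 h and 2 at 18 h and points to the structure of the samples. The splits within a harvest are too few (10) for a share under 0.05: at 18 h 3 splits gave as many as the real 1105 (highest other 1408, and 263 among the 4 splits that part all 3 number pairs), at 48 h 1 split gave 5289 (highest other 3548), and in mock leaves 2 gave 1179 (highest other 1355).

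Mock 48 h array 1-1 stood apart from its group, with an infection index of 0.513 against 0.175 and 0.123 for the other mock 48 h arrays, though these helped to set the index. The authors' scaling is excluded, since the index stayed at 0.476 after quantile normalization, above the range of the other 48 h mock arrays. An exchange with an 18 h array stays open: 0 arrays labelled 18 h had an infection index under 0.25 with a harvest index of 0.5 or more, and 1, mock 18 h array 1-2 at 0.399, lay below 0.5 by less than the range of the reference arrays. That array is itself a reference array, inside their range, and lay far from the other 48 h mock arrays (0.991 and 0.946). The count is thus no evidence for an exchange, and no 48 h mock array of its first number is left to rule one out. Infection of mock leaves alone and an 18 h sample under a 48 h label cannot be told apart: the harvest index was -0.0726 in its first version, 0.341 in its second and 0.390 in its last, inside the range of 0.254 to 0.422 of the 3 reference 18 h arrays, but the requirement that it differ from 0.5 by more than their range (0.169) was set after 0.390 was seen.

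Infected 18 h array 1-1 lay further along the infection index (1.11) than the rest of its group (0.516 and 0.539), and infected 48 h array 1-1 less far (0.774) than the rest of its own (array 2-1 at 1.26). The other infected 48 h arrays helped to set the index, so that the lower value of infected 48 h array 1-1 may be partly built in. Scaling is excluded, as the 18 h array still exceeded the 48 h array by 0.353 after quantile normalization. An exchange of these labels stays open, as does a difference in the speed of infection between leaves, which was not tested. Their harvest index differed by -0.0207 in the last version (0.634 and 0.655), while the first version gave 1.18 and 0.780 and the second 0.727 and 0.713. The index has no independent arrays to settle which label may be wrong.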
